A study of Mus musculus with 18 samples.

How the data were processed

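Hippocampal RNA of 18 samples in 4 groups (vehicle or cannabis extract, killed at P28 or as adults, n = 4 or 5) was measured on Illumina mouse bead arrays with biotin-labelled cRNA. The values used are the log2 probe intensities of the authors' deposited value table, in which every column holds the same distribution (median 6.86, range 6.50 to 15.08), so the authors had normalized them between arrays, apparently by quantiles. They were not background-subtracted, since unexpressed probes form a peak at 6.77, so fold changes are compressed, most of all for dim probes. Partek is named in the submitters' processing notes, with no version or step, and how each step was done is not given in the sources used here.

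The design fixed before the data were examined called for background correction and quantile normalization of the non-normalized signals (neqc), with a filter on detection p. Those signals, and a second normalized table, have columns named by slide position, which match no sample label, so their 72 per-sample columns were not used. The tests were therefore run on the log2 values described above. In place of detection p, a probe was kept if it exceeded 6.98, the peak of unexpressed probes plus 3 SD (SD 0.0702, from the lower side of the peak), in at least 4 arrays. This kept 18250 of 45281 probes. Slides could not be modelled for the same reason, since columns were matched to samples by name and never by order or values. The order of deposit of the samples was used instead, as 3 sets of 6, as a block and each set by itself, and whether these are slides is not known here. Gene symbols came from the platform annotation given, with symbols updated for 10 probes through the RefSeq gene table (assembly GRCm38.p6, no coordinates used): 34885 probes have 1 symbol, 18 several and 10378 are unnamed here, 2597 of those among the probes kept.

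Probes were fitted in limma 3.58.1 (R 4.3.3) with a mean for each of the 4 groups over all 18 arrays, 6 contrasts, moderated 2-sided tests and Benjamini-Hochberg adjustment over the probes kept, at 0.05. The residual and prior degrees of freedom were 14 and 3.93. Errors of fold changes are the moderated SE. Of 21 gene lists and 15 marker lists fixed before the data were examined, 35 were tested on 1 probe per gene, the one with the highest mean, with limma's camera at an inter-gene correlation of 0.01, and with an estimated correlation and fry beside it, adjusted over lists within a contrast. The sex-linked list had 3 members above background and is given in the observations gene by gene. List levels per array were compared with exact 2-sided permutation tests.

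Named genes follow a rule fixed before the data were examined. For the P28, adult, averaged and vehicle age contrasts these are the 8 largest rises and falls past the threshold, or, if fewer than 5 passed in a direction, the 5 with the smallest p there. For each list described, up to 3 members with the smallest p are added. Cnr1, Cnr2, Faah, Mgll, Napepld, Dagla and Daglb are given in every contrast, and the 5 genes with the smallest p in the interaction. Genes outside the rule are the members that moved against their list, and the few probes called in cannabis mice.

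Replicate numbers of the labels were checked for pairing before fits were compared. At P28 the deviations of same-numbered vehicle and cannabis arrays correlated at 0.196, 0.339, 0.383 and 0.534, all above 0.1. These arrays were taken as pairs, though no label says so and arrays of 1 set may correlate too. In adults and between ages some pairs fell below 0.1, so there the numbers only name samples. Where the other probes of a named gene went the other way this is said beside it, except for Faah, Mgll, Daglb and Napepld, whose small changes differ in sign between probes in some contrasts. No arrays were duplicates (correlations within groups of 0.971 to 0.994).

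Alternatives fixed before the data were examined were no filter, a trend and robust prior, array weights, only the groups compared, the replicate block, averaging the probes of a gene, leaving out each array, and a fold change of 1.2 as well. Chosen after seeing the data were a block or separate fits for replicates 4 and 5 against 1 to 3, the 3 sets of 6 in the order of deposit as a block or in separate fits, normexp background correction (offset 16) of the unlogged values, the choroid plexus level as a covariate, the background level exceeded in all 18 arrays, and several of these for lists.

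The tests were tested on simulated data with the real means and spreads, in which 200 of 18250 probes were changed. A log2 change of 0.50 was recovered in 72.5% of probes for the P28 contrast, 81.0% for adults and 80.5% for age in vehicle mice. A log2 change of 0.25 was recovered in 3.5%, 25.5% and 18.0%. A list of 19 genes shifted by 0.20 at P28 ranked 1 of 35 lists.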

Results

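Hippocampal RNA from 18 C57BL/6J mouse samples was profiled on Illumina bead arrays. Young mice were fed a cannabis extract at 20 mg/kg per day, or vehicle, for 14 days from postnatal day 14 to 28. One set was killed at P28, 70 to 80 min after the start of feeding, with 4 vehicle and 4 cannabis arrays. The other set was killed as adults (P56 in the labels), with 5 vehicle and 5 cannabis arrays. The adults had also been through behavioural tests and a phencyclidine challenge followed by a 2-week washout, so age and this history cannot be separated. Of 45281 probes, 18250 were above background in at least 4 arrays and stood for 10436 named genes. The number of arrays limits the precision. The labels do not say whether each array is a separate mouse, so the p-values measure the spread between these samples, which may be technical. The Y-linked genes Eif2s3y and Kdm5d were above background on 18 of 18 arrays by their brighter probes, and Xist on 0.

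Arrays numbered 4 and 5 stood apart from arrays 1 to 3 in each of the 4 groups. The first component of the deviations from the group means, which held 40.0% of the variance, separated them, and 4311 probes differed between the 2 sets within groups by limma (2191 higher and 2120 lower in replicates 4 and 5). At P28 only replicate 4 of each group is in the later set, against replicates 4 and 5 in adults. Values with this division as a block, and within each part, are given beside the gene lists. These 6 arrays are the last 6 of the 18 samples in the order of deposit, and the labels name no batch for them. The 3 sets of 6 in that order hold 4, 2 and 2 P28 and 2, 4 and 4 adult arrays, so set and age are partly tied. The second set differed from the first in 26 probes within groups by limma. The third set is replicates 4 and 5. Fits within a set have 2 residual degrees of freedom, with 2 arrays against 2 at P28 and 1 against 1 in adults in the first, and the reverse in the others. Both divisions were chosen after seeing the data. As a block each leaves the mean change of each list as it was for cannabis against vehicle, because each part holds as many arrays of both treatments.

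The first comparison asks what the extract did to hippocampal transcripts directly after dosing, at P28. Genes of interferon response and antigen presentation were lower in cannabis mice: all 13 measured members lay below vehicle, with a mean log2 fold change of -0.23 ± 0.21 (SD over members). Ifit3, an interferon-induced antiviral gene, was at 8.04 ± 0.06 with cannabis and 8.71 ± 0.26 with vehicle (log2 intensity, SD, n = 4 each), a log2 difference of -0.67 ± 0.13 (SE). Oasl2, of the same antiviral programme, differed by -0.51 ± 0.10, and B2m, the invariant chain of MHC class I, by -0.36 ± 0.08. For each of these 3 genes every vehicle array was above every cannabis array. The list fell by camera (adjusted p = 1.1e-16), and also with an estimated correlation (adjusted p = 0.023) and by fry (adjusted p = 0.0463). Over all probes 0 members passed and 4 did when adjusted over the list alone (B2m, Ifit3, Oasl2 and Usp18). The list level was 7.92 ± 0.08 with cannabis and 8.15 ± 0.10 with vehicle (SD, n = 4 each), with an exact permutation p of 0.0571, adjusted to 0.400 over 35 lists, where 0.0286 is the smallest p 4 against 4 arrays can give. The mean change was -0.31 within replicates 1 to 3 and 0.006 in replicate 4, which is 1 array against 1, so the direction was not seen there. With replicates 4 and 5 as a block it was -0.23 (adjusted p = 7.41e-16).

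Markers of choroid plexus epithelium, the tissue inside the ventricles that makes cerebrospinal fluid, were higher in P28 cannabis mice in all 15 members, with a mean log2 fold change of 0.76 ± 0.72 (SD). Ttr, the transthyretin of that tissue, differed by 2.74 ± 0.84 (SE), Ecrg4 by 1.39 ± 0.41 and the water channel Aqp1 by 0.85 ± 0.22. The list rose by camera (adjusted p = 1.89e-29) and with an estimated correlation (adjusted p = 0.0338), but not by fry (adjusted p = 0.144). Adjusted over the list alone 14 members passed, and 0 over all probes. Arrays within a group differed widely: Ttr was at 11.66, 14.20, 13.60 and 14.47 with cannabis and at 10.84, 9.63, 13.75 and 8.72 with vehicle. The level of the list had an exact permutation p of 0.0571 (n = 4 each). The mean change was 0.47 within replicates 1 to 3 and 1.62 in replicate 4, and 0.76 with the block. It was 0.68 in the first set of 6 and 0.06 in the second, 1 array against 1, where the call was lost (adjusted p = 0.226) and Ttr turned (-0.15). Without P28 cannabis replicate 1 the mean was 1.03, and Aqp1 and Ecrg4 passed in limma (adjusted p = 0.0221 for both).

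Immediate early genes, which neurons switch on within minutes of activity, were higher in 20 of 23 members at P28 with cannabis, with a mean of 0.18 ± 0.16 (SD). Egr1 differed by 0.27 ± 0.08 (SE), Dusp1 by 0.40 ± 0.13 and Egr2 by 0.36 ± 0.13. The list rose by camera (adjusted p = 2.83e-10) and with an estimated correlation (adjusted p = 0.0338), not by fry (adjusted p = 0.144). No member passed, over all probes or adjusted over the list alone (0 and 0). Every cannabis array was above every vehicle array in list level, which were at 8.94 ± 0.08 and 8.76 ± 0.02 (SD, n = 4 each; exact permutation p = 0.0286, adjusted 0.400). The change was 0.20 within replicates 1 to 3, 0.12 in replicate 4 and 0.18 with the block.

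Glucocorticoid-responsive genes were higher in 16 of 19 members, with a mean of 0.15 ± 0.19 (SD), and the list rose by camera (adjusted p = 8.17e-06). This was lost with an estimated correlation (adjusted p = 0.279). Sgk1, a kinase induced by corticosteroids, was at 12.29 ± 0.27 with cannabis and 11.64 ± 0.26 with vehicle (SD, n = 4 each), Cdkn1a differed by 0.31 ± 0.11 (SE) and Fkbp5 by 0.21 ± 0.08. Sgk1 was the 1 member past the threshold when adjusted over the list alone, with 0 over all probes. The change was 0.15 within replicates 1 to 3 and 0.13 in replicate 4, where the call was lost (adjusted p = 0.109). Microglial markers were lower in 15 of 18 members, with a mean of -0.11 ± 0.10 (SD). The list fell by camera (adjusted p = 9.55e-06), and this was lost with an estimated correlation (adjusted p = 0.135). Laptm5 differed by -0.31 ± 0.08 (SE), Csf1r by -0.16 ± 0.08 and Fcer1g by -0.15 ± 0.10. Laptm5 was the 1 member to pass when adjusted over the list alone. The change was -0.10 within replicates 1 to 3 and -0.13 in replicate 4. Every vehicle array was above every cannabis array in the level of the microglial list (exact permutation p = 0.0286, adjusted 0.400).

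No single probe passed at P28 in limma (0 at adjusted p 0.05, lowest 0.909), and 327 had an unadjusted p under 0.05 where 912 are expected by chance. Leaving out P28 cannabis replicate 1 gave 11. By camera 5 lists passed, and 8 without adult cannabis replicate 2. The same-numbered arrays, taken as pairs at P28, all differed in the direction of the list mean for choroid plexus, immediate early, glucocorticoid-responsive and microglial genes (4 of 4 pairs, paired exact permutation p = 0.125 each, the smallest 4 pairs allow). For interferon genes 3 of 4 pairs did (paired exact permutation p = 0.25). In the first and second sets of 6 the means were -0.26 and -0.42 for interferon genes, 0.15 and 0.30 for immediate early genes, 0.13 and 0.20 for glucocorticoid-responsive genes and -0.11 and -0.08 for microglial markers, the last not called in the second (adjusted p = 0.150). The choroid plexus level as a covariate, added after seeing the data, gave a mean of -0.34 for the interferon list and 0.245 for immediate early genes, and oligodendrocyte markers passed at -0.43 (adjusted p = 3.37e-13, main -0.05). The genes with the smallest p among those higher were Coq5, of coenzyme Q synthesis (0.22 ± 0.05), Cab39l (0.40 ± 0.10), Aqp1, Sgk1 and Itpripl1 (0.29 ± 0.08). Those lower were Ifit3, Oasl2, B2m, Rfesd (-0.26 ± 0.06) and the interferon-induced Ifitm1 (-0.31 ± 0.07). Cnr1, the CB1 cannabinoid receptor, differed by 0.09 ± 0.06, and the endocannabinoid enzymes Faah by -0.007 ± 0.111, Mgll by 0.02 ± 0.18, Napepld by 0.11 ± 0.12 and Daglb by 0.02 ± 0.09. Cnr2 and Dagla were on the array but below the background level used.

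**Figure D1:**
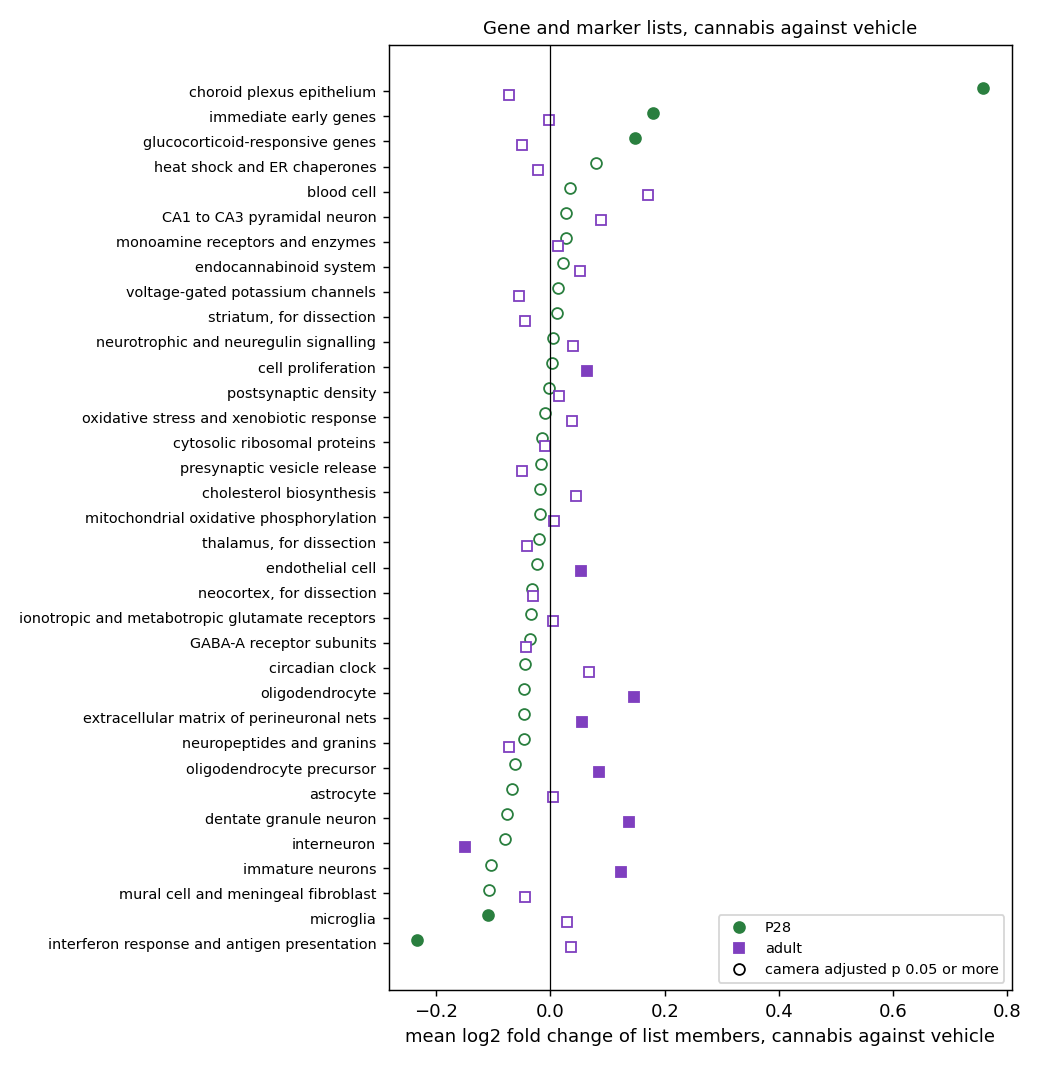
Mean log2 fold change of each list's members, cannabis against vehicle, at P28 (circles) and in adults (squares); filled symbols had a camera adjusted p below 0.05. Choroid plexus markers at P28 lie at 0.76 and the interferon list at -0.23, and the same lists lie at -0.07 and 0.04 in adults.

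**Figure D2:**
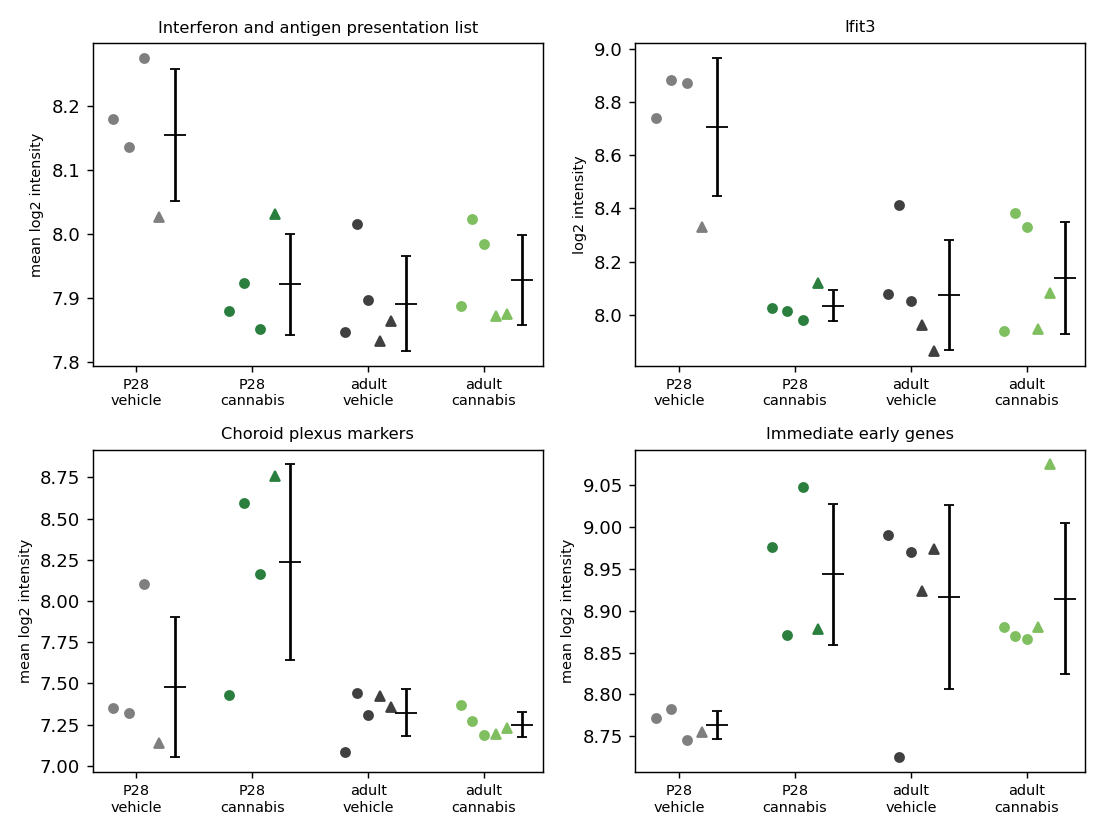
Log2 intensity per array of the interferon list, Ifit3, choroid plexus markers and immediate early genes in the 4 groups (n = 4, 4, 5 and 5); triangles are replicates 4 and 5, bars the group mean and SD. For Ifit3 the 4 P28 vehicle arrays lie above the 4 P28 cannabis arrays, with means of 8.71 and 8.04.

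The second comparison asks what remained in adults weeks after dosing ended. Interneuron markers were lower with cannabis in 14 of 16 members, with a mean log2 fold change of -0.15 ± 0.16 (SD). The vesicular GABA transporter Slc32a1 differed by -0.18 ± 0.07 (SE), the GABA-synthesizing enzyme Gad2 by -0.16 ± 0.07 and the neuropeptide Cort by -0.38 ± 0.16. The list fell by camera (adjusted p = 0.000376), and this was lost with an estimated correlation (adjusted p = 0.249) and by fry (adjusted p = 0.443). No member passed over all probes (0) or adjusted over the list alone (0). The mean change was -0.31 within replicates 4 and 5 but -0.04 within replicates 1 to 3, where the call was lost (adjusted p = 0.340), and -0.15 with the block. Leaving out adult cannabis replicate 4 gave -0.10 and ended the call (adjusted p = 0.057). The mean was -0.16 in the first set of 6 (adjusted p = 0.0936) and 0.02 in the second (0.964).

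The other 7 lists past the camera threshold in adults had means above 0 with cannabis, and none passed with an estimated correlation (adjusted p from 0.249 to 0.645). Dentate granule markers averaged 0.14, in 6 of 6 members (Prox1 0.27 ± 0.13 and Rfx3 0.27 ± 0.12, SE, and Trpc6 0.12 ± 0.14). Immature neuron genes averaged 0.12, in 12 of 15 members (Igfbpl1 0.35 ± 0.14, Marcksl1 0.47 ± 0.24, Dpysl5 0.23 ± 0.13). Oligodendrocyte markers averaged 0.15, in 14 of 19 (Mal 0.52 ± 0.27, Tspan2 0.41 ± 0.21, Mobp 0.25 ± 0.19), and oligodendrocyte precursor markers 0.09, in 7 of 8 (Cspg4 0.12 ± 0.05, Pdgfra 0.22 ± 0.12, Bmp4 0.17 ± 0.11). Endothelial markers averaged 0.05 (Sox18 0.17 ± 0.07, Slco1a4 0.16 ± 0.07, Eng 0.09 ± 0.05), cell proliferation genes 0.06 (Nusap1 0.17 ± 0.07, Ccnd1 0.17 ± 0.09, Mcm4 -0.10 ± 0.06) and genes of the perineuronal net matrix 0.06 (Hapln1 0.19 ± 0.06, Ncan 0.31 ± 0.12, Hapln4 -0.38 ± 0.16). Their adjusted p by camera ran from 0.0368 to 0.0494. No member passed over all probes (0), and Hapln1 was the only one past the threshold when adjusted over its list alone. Leaving out 1 array moved the means to between 0.09 and 0.19 for dentate granule markers, 0.06 and 0.17 for immature neuron genes, 0.04 and 0.24 for oligodendrocyte markers, 0.035 and 0.13 for precursors, 0.02 and 0.08 for endothelial markers, 0.035 and 0.09 for proliferation genes and 0.03 and 0.07 for the perineuronal net. None of these 7 lists passed within replicates 1 to 3 alone. The means within replicates 1 to 3 and within 4 and 5 were 0.09 and 0.21 for dentate granule markers, 0.11 and 0.14 for immature neuron genes, 0.18 and 0.13 for oligodendrocyte markers, 0.06 and 0.12 for precursors, 0.02 and 0.10 for endothelial markers, 0.04 and 0.10 for proliferation genes and 0.03 and 0.10 for the perineuronal net. Within replicates 4 and 5 dentate granule and endothelial markers passed and the other 5 did not (adjusted p from 0.0515 for proliferation genes to 0.317 for oligodendrocyte markers). With the block the oligodendrocyte list (adjusted p = 0.0533) and the perineuronal net list (adjusted p = 0.0552) were lost. The number of lists past the threshold in adults was 0 without adult cannabis replicate 4, 1 without adult cannabis replicate 2, 2 without any one of adult cannabis replicate 3 and adult vehicle replicates 3, 4 and 5, 4 without adult vehicle replicate 2 and 5 without P28 vehicle replicate 1. With the 3 sets of 6 as a block 2 adult lists passed, interneuron (adjusted p = 0.000339) and dentate granule markers (0.013), and the other 6 did not (0.0527 to 0.0547). In the first set of 6, 1 array against 1, oligodendrocyte markers passed (mean 0.56) and the means of the other 6 of these lists were below 0. In the second, dentate granule (0.16), endothelial (0.09) and immature neuron genes (0.23) passed, and oligodendrocyte markers were at -0.05. The other Marcksl1 probe went the other way.

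By limma 0 probes passed in adults (lowest adjusted p = 0.880), with 647 at an unadjusted p under 0.05. Egr1, an activity-induced transcription factor, was at 12.59 with cannabis and 12.24 with vehicle, a log2 difference of 0.35 ± 0.07 (SE), and the 5 cannabis arrays were above the 5 vehicle arrays. Other genes with the smallest p among those higher were Igfbp4 (0.31 ± 0.07), Wdr61 (0.23 ± 0.06), Eif3c (0.33 ± 0.09) and Dgcr8 (0.25 ± 0.07). Among those lower were 2900060B14Rik (-0.71 ± 0.15), Slc38a2 (-0.41 ± 0.11), Luzp2 (-0.29 ± 0.08), Ccnd2 (-0.38 ± 0.11) and Dnajc7 (-0.37 ± 0.10). One of the 2 other Slc38a2 probes went the other way. Cnr1 differed by -0.06 ± 0.05, Faah by 0.11 ± 0.10, Mgll by 0.19 ± 0.16, Napepld by -0.06 ± 0.10 and Daglb by 0.08 ± 0.08.

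The third comparison tests whether the cannabis effect differed between ages. P28 mice were killed 70 to 80 min after the start of feeding, adults weeks after dosing, behavioural tests and phencyclidine. These differences cannot be separated from age. By limma 0 probes passed, with 531 at an unadjusted p under 0.05, and Rfesd (0.36 ± 0.08), B2m (0.47 ± 0.10), Ifitm1 (0.40 ± 0.09), Coq5 (-0.29 ± 0.07) and Slc38a2 (-0.68 ± 0.16) had the smallest p. One of the 2 other probes of Coq5, and of Slc38a2, went the other way. Across lists 10 passed by camera (adult minus P28), and 0 with an estimated correlation (adjusted p of the 10 from 0.118 to 0.558) or by fry. The interferon list differed by 0.27, in 12 of 13 members, with 5 past the threshold when adjusted over the list alone, and by 0.35 within replicates 1 to 3 and 0.018 within 4 and 5. Choroid plexus markers differed by -0.83, in 15 of 15 members, with 10 past the threshold when adjusted over the list alone, and by -0.47 and -1.80 within the parts. Lower in the same sense were immediate early genes (-0.18, and -0.22 and -0.09 within the parts) and glucocorticoid-responsive genes (-0.20, and -0.18 and -0.22), with 1 member each past the threshold when adjusted over the list alone (Dusp1 and Sgk1). Higher were immature neuron genes (0.23, and 0.23 and 0.21), dentate granule markers (0.21, and 0.15 and 0.32), oligodendrocyte precursors (0.15, and 0.16 and 0.08), microglial markers (0.14, and 0.09 and 0.23), the perineuronal net (0.10, and 0.09 and 0.10) and endothelial markers (0.08, and 0.04 and 0.13), with 0 members past the threshold. Over all probes 0 members of these lists passed. The endothelial list was lost with the block (adjusted p = 0.0588) or with the 3 sets of 6 as a block (0.0628), and immature neuron genes with the choroid plexus level as a covariate (0.155, adjusted p = 0.207) as was the endothelial list (0.06, adjusted p = 0.246). Within replicates 4 and 5 the calls of interferon genes (adjusted p = 0.656), immediate early genes (0.352), oligodendrocyte precursors (0.349), the perineuronal net (0.283), glucocorticoid-responsive genes (0.0571) and endothelial markers (0.0511) were lost, and within replicates 1 to 3 those of endothelial markers (0.368) and the perineuronal net (0.068). In the first set of 6 only interferon (0.34), immediate early (-0.26) and glucocorticoid-responsive genes (-0.22) of the 10 passed, and in the second interferon (0.47), immediate early (-0.28) and choroid plexus genes (-0.20). Without adult cannabis replicate 4, 6 lists passed, and dentate granule markers (adjusted p = 0.0517) and oligodendrocyte precursors (adjusted p = 0.0517) were among those lost, as they were without P28 cannabis replicate 1 (0.0796 and 0.0678). Brackets now hold the mean log2 difference without the array. The perineuronal net was lost without P28 cannabis replicate 1 (0.067), P28 vehicle replicate 2 (0.081), adult cannabis replicate 3 (0.076) or 4 (0.10) or adult vehicle replicate 5 (0.075). Endothelial markers were lost without P28 cannabis replicate 1 (0.071), 2 (0.075) or 4 (0.063), P28 vehicle replicate 1 (0.067) or 2 (0.076), adult cannabis replicate 2 (0.052), 3 (0.078) or 4 (0.063), or adult vehicle replicate 3 (0.065) or 5 (0.045). Cnr1 differed by -0.15 ± 0.08, Faah by 0.12 ± 0.15, Mgll by 0.17 ± 0.24, Napepld by -0.16 ± 0.16 and Daglb by 0.05 ± 0.12. Across the 18250 probes, which are not independent replicates, the cannabis effects at the 2 ages had a Pearson r of -0.10 and a Spearman rho of -0.10, and 46.8% had the same sign. Without P28 cannabis replicate 3 the r was 0.04, and within the first set of 6, the second set and replicates 4 and 5 it was 0.26, 0.01 and 0.01.

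Averaged over both ages, 0 probes passed in limma, with 376 at an unadjusted p under 0.05. Egr1 had the lowest adjusted p (0.249), with a mean effect of 0.31 ± 0.05 (SE), and passed without adult cannabis replicate 3 (adjusted p = 0.0232), where the count was 1. Cog7 (0.22 ± 0.06), Edem2 (0.17 ± 0.05), Acbd5 (0.11 ± 0.03) and Mettl3 (0.19 ± 0.05) were also higher, and Rnf14 (-0.18 ± 0.05), Usp18 (-0.23 ± 0.06), Ifit3 (-0.30 ± 0.09), Rac3 (-0.12 ± 0.03) and Vwa5b2 (-0.21 ± 0.06) lower. Both other Rnf14 probes went the other way. Of 35 lists 6 passed by camera, and 0 with an estimated correlation (adjusted p of the 6 from 0.118 to 0.544) or by fry. They were immediate early genes (mean 0.09, with Egr2 0.28 ± 0.09 and Klf4 0.15 ± 0.06), choroid plexus markers (0.34, with Aqp1 0.43 ± 0.15, Ecrg4 0.66 ± 0.28 and Cldn2 0.20 ± 0.09), glucocorticoid-responsive genes (0.05, with Cdkn1a 0.18 ± 0.08, Arrdc2 0.12 ± 0.07 and Ddit4 -0.21 ± 0.12), interneuron markers (-0.11), neuropeptides and granins (-0.06) and the interferon list (-0.10, with Oasl2 -0.23 ± 0.07). Tac1 (-0.18 ± 0.08), Cort (-0.25 ± 0.12) and Sst (-0.21 ± 0.11) had the smallest p in both neuronal lists. Over all probes 0 members passed, and adjusted over the list alone Egr1 in the immediate early list and Ifit3, Oasl2 and Usp18 in the interferon list did. Within replicates 1 to 3 and within 4 and 5 the means were 0.09 and 0.08 for immediate early genes, 0.23 and 0.72 for choroid plexus markers, 0.07 and 0.02 for glucocorticoid-responsive genes, -0.07 and -0.16 for interneuron markers, -0.05 and -0.07 for neuropeptides and -0.14 and 0.015 for the interferon list, which turned there. Glucocorticoid-responsive genes (adjusted p = 0.494) and neuropeptides (0.108) did not pass within replicates 4 and 5, nor neuropeptides (0.105) within 1 to 3 or with the choroid plexus level as a covariate (0.188). In the first set of 6 the calls of immediate early (0.018) and glucocorticoid-responsive genes (0.022) were lost, and in the second those of interneuron markers (-0.033) and neuropeptides (-0.010), and choroid plexus markers turned (-0.042). Means without the array are given first in brackets. Glucocorticoid-responsive genes were lost without adult cannabis replicate 5 (0.019, adjusted p = 0.333), adult vehicle replicate 2 (0.029), P28 vehicle replicate 4 (0.036), P28 cannabis replicate 2 (0.044) or 3 (0.039), or adult cannabis replicate 3 (0.039). Neuropeptides were lost without P28 cannabis replicate 2 (-0.047, adjusted p = 0.166), P28 vehicle replicate 4 (-0.062), adult vehicle replicate 1 (-0.049) or 2 (-0.058), or adult cannabis replicate 1 (-0.062), 4 (-0.046) or 5 (-0.054). Cnr1 differed by 0.01 ± 0.04, Faah by 0.05 ± 0.08, Mgll by 0.11 ± 0.12, Napepld by 0.02 ± 0.08 and Daglb by 0.05 ± 0.06.

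The comparison of adult with P28 vehicle mice describes the age difference without the extract. Oligodendrocyte markers were lower in adults: 17 of 19 members lay below P28, with a mean log2 fold change of -0.90 ± 0.57 (SD), and 11 fell past the threshold over all probes and 14 when adjusted over the list alone. The list passed by camera, and this was lost with an estimated correlation (adjusted p = 0.0963). The log2 change was -1.54 ± 0.23 (SE) for Mag, a myelin glycoprotein, -1.46 ± 0.22 for Mog, -1.52 ± 0.31 for Ugt8a, which makes myelin lipids, -1.51 ± 0.31 for Opalin and -1.49 ± 0.25 for Cnp. Plekhb1 (0.18 ± 0.17) and Aspa (0.13 ± 0.09) were the members on the other side. Oligodendrocyte precursor markers averaged -0.37 (Bmp4 -0.63 ± 0.11, Gpr17 -1.26 ± 0.26 and Pdgfra -0.55 ± 0.13), with 3 past the threshold over all probes and 5 when adjusted over the list alone, and a camera call also lost with an estimated correlation (adjusted p = 0.0963). The oligodendrocyte level was 9.96 ± 0.27 in adults (SD, n = 5) and 10.85 ± 0.21 at P28 (n = 4), with no overlap (exact permutation p = 0.00794, the smallest these arrays allow, adjusted 0.0556). Mag, Mog and Cnp passed whichever array was left out. The other calls named here ended without any of several arrays: 6 for Ugt8a (highest adjusted p = 0.104, without P28 vehicle replicate 3), 7 for Opalin (0.0995, the same array), 2 for Bmp4 and 7 for Gpr17 (0.066 and 0.0922, without P28 vehicle replicate 2) and 9 for Pdgfra (0.153, without P28 vehicle replicate 1), by limma.

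The lists that follow passed by camera in the comparison of vehicle mice, and none did with an estimated correlation (adjusted p from 0.0963 to 0.421). Immature neuron genes averaged -0.37 in adult vehicle mice. Marcksl1 fell by 1.40 ± 0.26 and Igfbpl1 by 0.76 ± 0.15, Neurod2 differed by 0.44 ± 0.11, and 2 members fell over all probes (adjusted over the list alone, 9 fell and 1 rose). Cholesterol synthesis genes averaged -0.25, with Sqle (-0.61 ± 0.11), Cyp51 (-0.69 ± 0.14) and Fdps (-0.55 ± 0.13) past the threshold over all probes and 7 when adjusted over the list alone. Interferon and antigen presentation genes averaged -0.26 (Oasl2 -0.60 ± 0.10, B2m -0.38 ± 0.07, Ifitm3 -0.64 ± 0.13), with 5 past the threshold both over all probes and adjusted over the list alone. In cannabis mice the interferon mean with age was 0.006, with 8 members up and 5 down. This fall and that with cannabis at P28 share the 4 P28 vehicle arrays, whose list level was 8.15, with the other groups at 7.89 to 7.93. Blood cell genes averaged -0.78 (Hba-a1 -1.07 ± 0.23, Hbb-bt -0.96 ± 0.24, Alas2 -0.27 ± 0.08), with Hba-a1 past the threshold over all probes and 4 members when adjusted over the list alone. Endothelial markers averaged -0.10, with Vwf at -0.58 ± 0.14, Flt1 at 0.38 ± 0.11 and Esam at -0.26 ± 0.08, and 0 members past the threshold over all probes and 4 when adjusted over the list alone. Members are counted by the 1 probe tested per gene, and other probes of Mobp (lowest -1.88), Mal, Hbb-bs, Hbb-bt, Tubb2b and H2-D1 passed over all probes, all lower in adults. Higher in adults were heat shock and ER chaperones (mean 0.25, with Calr 0.55 ± 0.18, Hspa1a 0.44 ± 0.17 and Hspb6 -0.35 ± 0.12), immediate early genes (0.15, with Dusp1 0.31 ± 0.12 and Jun 0.35 ± 0.14) and voltage-gated potassium channels (0.11, with Kcnh1 0.54 ± 0.14, Kcnab2 0.16 ± 0.07 and Kcnq5 0.20 ± 0.11). In these 3 lists Inhba passed over all probes, and Inhba and Kcnh1 when adjusted over the list alone. By fry 7 of the 10 lists called by camera passed (adjusted p of the 10 from 0.0032 to 0.16), and 1 that camera did not call, the perineuronal net (0.0126). Within replicates 1 to 3, within 4 and 5 and with the block, the means were -0.37, -0.36 and -0.37 for immature neuron genes, -0.29, -0.11 and -0.25 for cholesterol genes, -0.27, -0.18 and -0.26 for interferon genes, -0.77, -0.58 and -0.73 for blood cell genes, -0.07, -0.13 and -0.09 for endothelial markers, 0.19, 0.33 and 0.24 for chaperones, 0.13, 0.19 and 0.15 for immediate early genes, 0.12, 0.11 and 0.12 for potassium channels and -0.35, -0.39 and -0.37 for oligodendrocyte precursors. Within replicates 1 to 3 endothelial markers (adjusted p = 0.214) and immediate early genes (0.0699) did not pass, and within 4 and 5 potassium channels (0.129) and cholesterol genes (0.073). The endothelial call was lost with the block (adjusted p = 0.0634). It was also lost without adult vehicle replicate 5 (mean -0.071, adjusted p = 0.171) or 3 (-0.092), P28 vehicle replicate 1 (-0.093) or 4 (-0.114), P28 cannabis replicate 1, 2 or 3 (-0.103 each), or adult cannabis replicate 3 or 4 (-0.103 each).

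Most single-gene calls in these lists ended in limma without any of several arrays. The number of such arrays, with the highest adjusted p, was 4 for Cyp51 (0.0933), 3 for Sqle (0.0759), 5 for B2m (0.0849) and 6 for Ifitm3 (0.0777), each highest without P28 vehicle replicate 3. It was 13 for Fdps (0.168) and 4 for Igfbpl1 (0.0784), highest without P28 vehicle replicate 2, and 6 for Hba-a1 (0.111), highest without P28 vehicle replicate 1, the 1 array whose removal ended the call of Marcksl1 (0.056). Oasl2 passed whichever array was left out. Dusp1 passed without adult vehicle replicate 2 (0.022), Jun without adult cannabis replicate 3 (0.0366) and Kcnh1 without adult cannabis replicate 4 (0.0484). Neurod2 passed without adult cannabis replicate 2 or 4, Hbb-bt without P28 vehicle replicate 4 or adult cannabis replicate 5, and Vwf without any of adult cannabis replicate 2 or 5 and P28 vehicle replicate 4.

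By limma 195 probes passed between ages in vehicle mice, 47 higher and 148 lower in adults, and 152 named genes were among them. The largest rises were Il33, an alarmin cytokine (1.12 ± 0.21, SE), 2900060B14Rik (0.88 ± 0.16), the activin subunit Inhba (0.72 ± 0.16), Itga11 (0.61 ± 0.14), Upf2 (0.56 ± 0.13), complement C4b (0.51 ± 0.11), Fgf10 (0.50 ± 0.11) and Slc26a4 (0.50 ± 0.11). Igf2, a growth factor, fell by 1.39 ± 0.24 (SE) and completes the 8 largest falls, by the 1 probe per gene, with Mag, Ugt8a, Opalin, Tspan2, Cnp, Mog and Marcksl1. Cnr1 differed by 0.06 ± 0.05, Faah by -0.09 ± 0.11, Mgll by -0.16 ± 0.17, Napepld by 0.29 ± 0.11 and Daglb by -0.06 ± 0.09, none past the threshold. The count was 554 with the 3 sets of 6 as a block, where the 10 lists called by camera also passed, 419 with replicates 4 and 5 as a block, 4 within replicates 1 to 3 and 0 within replicates 4 and 5 (1 P28 array against 2). It was 53, 35 and 28 without P28 vehicle replicates 1, 2 and 3, 69, 84, 61 and 94 without adult vehicle replicates 1, 3, 4 and 5, and 317 without adult vehicle replicate 2. The calls of the 8 rises ended without any of 4 arrays for Il33 (highest adjusted p = 0.0759), 2 for 2900060B14Rik (0.0759), 7 for Inhba (0.134), 9 for Itga11 (0.148), 10 for Upf2 (0.157) and 9 for C4b (0.135), each highest without P28 vehicle replicate 3, and 6 for Fgf10 (0.134) and 7 for Slc26a4 (0.153), highest without P28 vehicle replicate 1. That of Igf2 ended without P28 vehicle replicate 2 alone (0.0523). The oligodendrocyte mean was -1.001, -0.72 and -0.89 within replicates 1 to 3, within 4 and 5 and with the block, and -1.38 and -0.84 in the first and second sets of 6, where 0 probes passed.

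**Figure D3:**
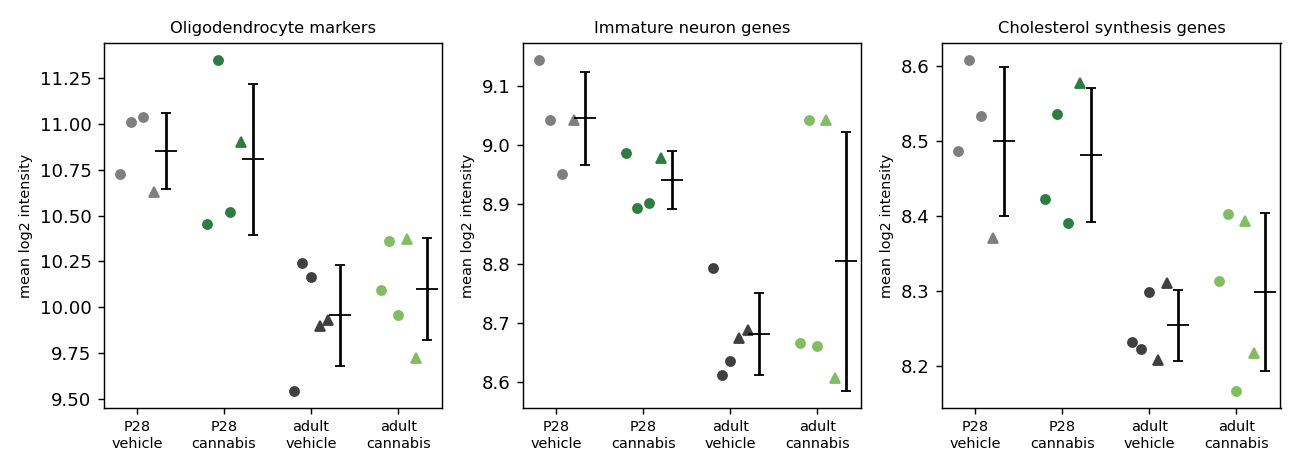
Mean log2 intensity per array of oligodendrocyte markers, immature neuron genes and cholesterol synthesis genes in the 4 groups (n = 4, 4, 5 and 5); triangles are replicates 4 and 5, bars the group mean and SD. Oligodendrocyte levels of adult vehicle arrays average 9.96 against 10.85 at P28.

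In cannabis mice the same age comparison gave 5 probes past the threshold by limma, all lower in adults, with 1937 at an unadjusted p under 0.05. They were 2 probes of the myelin gene Mobp (-0.61 ± 0.10 and -0.99 ± 0.16, SE), Ddr1 (-0.73 ± 0.12), Itpripl1 (-0.50 ± 0.08) and 1 probe with no gene name here. These genes were named after their values were seen. Across lists 10 passed by camera: oligodendrocyte markers (mean -0.71), oligodendrocyte precursor markers (-0.23), choroid plexus markers (-0.99), blood cell genes (-0.64), glucocorticoid-responsive genes (-0.22) and cholesterol synthesis genes (-0.18) were lower in adults, and dentate granule markers (0.31), circadian clock genes (0.18), heat shock and ER chaperones (0.15) and microglial markers (0.10) higher. None passed with an estimated correlation (adjusted p from 0.052 to 0.592), and 7 lists passed by fry. Over all probes 0 members of these lists passed by the 1 probe tested per gene, and Mobp did by the 2 other probes above. Adjusted over the list alone 14 oligodendrocyte, 14 choroid plexus, 4 blood cell, 3 glucocorticoid-responsive, 3 cholesterol, 2 precursor and 1 chaperone gene fell, and 3 dentate granule and 1 microglial gene rose. Within replicates 1 to 3, within 4 and 5 and with the block, the means were -0.67, -0.86 and -0.70 for oligodendrocyte markers, -0.19, -0.31 and -0.22 for precursors, -0.79, -1.55 and -0.996 for choroid plexus markers, -0.67, -0.47 and -0.59 for blood cell genes, -0.27, -0.08 and -0.22 for glucocorticoid-responsive genes, -0.16, -0.27 and -0.18 for cholesterol genes, 0.23, 0.40 and 0.29 for dentate granule markers, 0.16, 0.15 and 0.16 for clock genes, 0.13, 0.20 and 0.14 for chaperones and 0.09, 0.10 and 0.10 for microglial markers. With the choroid plexus level as a covariate the oligodendrocyte mean was -0.21 (adjusted p = 0.101), precursors -0.16 (0.101), cholesterol genes -0.08 (0.230) and clock genes 0.15 (0.0647), none past the threshold by camera. Blood cell (adjusted p = 0.246), glucocorticoid-responsive (0.321) and microglial genes (0.0957) did not pass within replicates 4 and 5. The probe count was 141 with the 3 sets of 6 as a block, where the 10 lists also passed, 8 with replicates 4 and 5 as a block, 0 within replicates 1 to 3 and 32 within replicates 4 and 5. It was 102 without P28 cannabis replicate 1, 32 without adult cannabis replicate 2, 15 without adult vehicle replicate 1 or 2, 8 without P28 vehicle replicate 3, 2 without P28 cannabis replicate 2 or adult cannabis replicate 4 and 1 without adult cannabis replicate 5. Without P28 vehicle replicate 4 it was 7, and without each of the 9 other arrays 0. Chaperones were lost without P28 cannabis replicate 1 (0.09, adjusted p = 0.177) or adult cannabis replicate 1 (0.10, 0.0868), and precursors without P28 cannabis replicate 4 (-0.20, 0.117), adult cannabis replicate 1 (-0.20, 0.0878) or adult cannabis replicate 3 (-0.21, 0.0702). Cnr1 differed by -0.09 ± 0.05, Faah by 0.03 ± 0.11, Mgll by 0.01 ± 0.17, Napepld by 0.13 ± 0.11 and Daglb by -0.008 ± 0.088. The age effects in vehicle and cannabis mice, which share no array, correlated across probes with r = 0.61, and 67.0% of the 18250 probes had the same sign. Of the 195 probes called in vehicle mice 187 (95.9%) did, with a median ratio of 0.604, which their selection for large effects in vehicle mice lowers by itself. Only 3 were called in both, but the interaction test, which asks whether the age effects differ, called 0. The oligodendrocyte level in cannabis mice was 10.10 ± 0.28 in adults (SD, n = 5) and 10.81 ± 0.41 at P28 (n = 4), with no overlap (exact permutation p = 0.00794, adjusted 0.139). In the first and second sets of 6 the mean was -0.85 and -0.36, and 0 probes passed.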

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

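The 7 tests of explanations for the 3 patterns weighed below, and the paired test, were chosen only after the result was seen, and the counts over other splits of the arrays were chosen before. Dixon's test for 1 array far from the rest of its group was run on 268 groups of 4 or 5 arrays and found 17 values, where chance gives about 1 in 20 groups.

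Among gene lists, the microglial level of adult cannabis replicate 1 was 7.86, with the others at 7.96 to 7.99 (log2 intensity). Immediate early genes were at 8.72 in adult vehicle replicate 2 (others 8.92 to 8.99) and at 9.07 in adult cannabis replicate 5 (others 8.87 to 8.88). Chaperones were at 8.95 in P28 vehicle replicate 1 (others 9.08 to 9.09). Among genes of the P28 comparison, Aqp1 was at 7.49 in P28 vehicle replicate 3 (others 6.79 to 6.9) and at 7.06 in adult vehicle replicate 4 (others 6.73 to 6.8), and B2m at 10.95 in P28 vehicle replicate 3 (others 10.66 to 10.67). Coq5 was at 10 in adult cannabis replicate 1 (others 9.88 to 9.91) and Ifitm1 at 7.41 in adult vehicle replicate 3 (others 7.52 to 7.56). Daglb was at 9.28 in P28 cannabis replicate 2 (others 9.47 to 9.5) and at 9.7 in adult vehicle replicate 2 (others 9.2 to 9.33), the array in which Upf2 was at 11.19 (others 11.72 to 11.86). Wdr61 was at 9.93 in P28 vehicle replicate 2 (others 9.79 to 9.8), Dnajc7 at 9.75 in P28 cannabis replicate 4 (others 10.06 to 10.1) and Rnf14 at 12.08 in P28 cannabis replicate 2 (others 12.25 to 12.26). Cog7 was at 7.68 in adult cannabis replicate 3 (others 7.35 to 7.42) and Rac3 at 7.02 in adult cannabis replicate 5 (others 6.87 to 6.91).

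The cannabis effect differed between ages in 10 lists by camera on the interaction (adult minus P28), and in none with an estimated correlation. The ages also differ in time since dosing and in history. The difference was -0.831 for choroid plexus markers (adjusted p = 1.12e-16, and 0.17 with an estimated correlation), 0.269 for interferon genes (5.03e-11 and 0.118), 0.137 for microglial markers (0.00024 and 0.203), -0.197 for glucocorticoid-responsive genes (0.000785 and 0.358) and -0.182 for immediate early genes (0.000896 and 0.298). It was 0.228 for immature neuron genes (0.00252 and 0.3), 0.148 for oligodendrocyte precursors (0.0117 and 0.298), 0.213 for dentate granule markers (0.0148 and 0.183), 0.101 for the perineuronal net (0.0274 and 0.17) and 0.0769 for endothelial markers (0.0455 and 0.558).

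Other splits of the same arrays show whether chance can be excluded for the probe counts. For age in vehicle mice 1 of 100 splits, the real one, gave as many as 195 probes, with 137 the highest of the others. The count was 99 with no filter and 375 on the groups compared alone, and set and age are partly tied. Chance is therefore argued against but not firmly excluded. For age in cannabis mice 2 of 100 splits gave 5 or more, since the highest other split tied the real count of 5. That count was 0 with no filter on dim probes and 0 on the groups compared alone, so chance cannot be firmly excluded there. For the counts of 0 by limma every split gives at least as many, so the comparison was fixed and says nothing about chance. At P28 it was 35 of 35 splits, the highest other 28, and the 7 others that part all same-numbered pairs gave at most 0. In adults it was 100 of 100, the highest other giving 1580. That split keeps replicates 4 and 5 together, which points to a structure of the samples, and with that division as a block the adult count is also 0. The interaction and the average gave 100 of 100 each, with 11 as the highest other in both. The correlation of the cannabis effects at the 2 ages was -0.102, and 71 of 100 splits gave one at least as far from 0, up to -0.727, so chance cannot be excluded.

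Interferon genes were lower with cannabis at P28. A single array is argued against, since the mean change nearest to 0 after leaving out 1 P28 array was -0.192. Dependence on the set of arrays stays open, since the replicate 4 pair showed no fall. Leaving it out could only enlarge the change, to -0.312 (95% interval -0.44 to -0.184, 3 against 3 arrays, normal spread assumed). Fewer microglia in the cannabis arrays cannot be told apart from a lower interferon response, because interferon genes differed from microglial markers by -0.124 with an exact permutation p of 0.171, which leaves both open. An effect of the extract stays open, and litter or cage, which the labels do not give, were not tested.

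Choroid plexus markers were higher with cannabis at P28. Choroid plexus tissue carried over in different amounts may be the source: within groups Ttr followed the mean of the 14 other markers over 18 arrays with a Pearson r of 0.782 (permutation p = 7e-05) and a Spearman rho of 0.858 (permutation p = 0.00013), and r was 0.738 without the 2 arrays farthest from the median. This r lies below the bound of 0.8 set for that explanation, and choroid genes regulated together would correlate too, so the explanations cannot be told apart. A chance difference in carry-over between the 8 arrays cannot be told apart either: the exact permutation p of the list level was 0.0571 without pairing, and the same-numbered pairs differed by 0.082, 1.27, 0.061 and 1.62, all 4 one way, with a paired exact permutation p of 0.125, the smallest 4 pairs can give. An effect of the extract on this tissue stays open as untested.

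Oligodendrocyte markers were lower in adult than in P28 vehicle mice. The list level there had an exact permutation p of 0.00794, adjusted to 0.0556 over 35 lists, and the list did not pass with an estimated correlation (adjusted p = 0.0963). Chance variation of white matter from array to array is argued against by the cannabis mice, which share no array with these: the level differed there by -0.707 (vehicle -0.898) without overlap (exact permutation p = 0.00794, adjusted 0.139). Over all 15876 relabellings of age within treatment the exact permutation p was 6.3e-05, adjusted to 0.0022 over 35 lists. This treats each array as a separate sample. Another dissection border in adults cannot be told apart from age. The markers of 3 neighbouring regions had a smallest exact permutation p of 0.222 (thalamus -0.0754, p = 0.333, neocortex 0.0259, p = 0.778, and striatum 0.0547, p = 0.222). A p that misses the threshold does not show that these regions did not differ. Choroid plexus markers were not among them. Their level fell with age by -0.572 over both treatments (exact permutation p = 0.00907, adjusted 0.0397). The fall was -0.987 in cannabis mice and -0.157 in vehicle mice (exact permutation p = 0.619 in vehicle mice), so a difference in dissection stays open. Age and the tests and phencyclidine that only adults received stay open as untested.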

How the results depend on the processing

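The tests added only after the result was seen are normexp background correction, the level exceeded in all arrays, the block and separate fits for replicates 4 and 5 against 1 to 3, the block of 3 sets of 6 in the order of deposit and fits within a set, the choroid plexus covariate, for lists the fits on own groups, averaged probes and left-out arrays, and for the correlation every setting except no filter and left-out arrays. Numbers in brackets are mean log2 changes of lists or log2 changes of genes. Apart from effects of an alternative's own construction named below, the cause was not tested. Signal over background limits the dim probes, whose fold changes are compressed because background was not removed.

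No filter on dim probes was the first alternative. In adults, calls lost were oligodendrocyte (0.13) and perineuronal net (0.024). Between ages, calls lost were endothelial (0.068) and perineuronal net (0.040). Between the ages of vehicle mice, probes called came to 99. From P28 to adult with cannabis, probes called came to 0 and calls lost were blood (-0.25). Next, probes had to exceed the level in all 18 arrays, so fewer genes were tested. In adults, lists called came to 3 and calls lost were precursors (0.065), endothelial (0.057), perineuronal net (0.034), proliferation (0.071) and immature neurons (0.11). For the difference between ages, calls lost were precursors (0.13), endothelial (0.079) and perineuronal net (0.065). Averaged, calls lost were neuropeptides (-0.069). In vehicle mice across ages, calls lost were endothelial (-0.11). In cannabis mice across ages, probes called came to 20 and calls lost were precursors (-0.27). Normexp background correction was tried. In adults, calls lost were perineuronal net (0.079). Across ages in cannabis mice, probes called came to 15.

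A trend and robust prior was tried. With age in cannabis mice, probes called came to 12. Array quality weights were tried. At P28, the sign turned for Faah (0.007). Averaged, the sign turned for Cnr1 (-0.003) and Napepld (-0.014). Across ages in vehicle mice, probes called came to 850. For age in cannabis mice, probes called came to 0. Fits on the groups compared alone were tried. At P28, lists called came to 8. In adults, calls lost were perineuronal net (0.055) and proliferation (0.064). With age in vehicle mice, probes called came to 375 and calls lost were endothelial (-0.10). From P28 to adult with cannabis, probes called came to 0. The probes of a gene were averaged. At P28, lists called came to 8 and the sign turned for Faah (0.003). In adults, calls lost were perineuronal net (0.033). For age in vehicle mice, the sign turned for Faah (0.018) and Daglb (0.014). In cannabis mice across ages, probes called came to 9.

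With the replicate number as a block, pairing was assumed at P28 from the check described with the processing, and elsewhere the numbers are shared only by name. In the interaction, calls lost were endothelial (0.077). Between the ages of vehicle mice, probes called came to 359 and calls lost were endothelial (-0.076). Across ages in cannabis mice, probes called came to 53 and calls lost were chaperones (0.099). With this block 6 lists passed at P28, chaperones (0.079) newly, 9 lists passed in adults, neuropeptides (-0.072) newly and 10 lists passed in the interaction, oligodendrocyte (0.19) newly. With replicates 4 and 5 against 1 to 3 as a block, further calls were lost. In adults, calls lost were oligodendrocyte (0.15) and perineuronal net (0.055). Between ages, calls lost were endothelial (0.077). In vehicle mice across ages, probes called came to 419 and calls lost were endothelial (-0.094). With age in cannabis mice, probes called came to 8. With the 3 sets of 6 in the order of deposit as a block, counts and calls moved as follows. In adults, lists called came to 2 and calls lost were oligodendrocyte (0.15), precursors (0.085), endothelial (0.054), perineuronal net (0.055), proliferation (0.064) and immature neurons (0.12). For the difference between ages, calls lost were endothelial (0.077). Across ages in vehicle mice, probes called came to 554. For age in cannabis mice, probes called came to 141.

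With an estimated correlation the means are by construction as reported and only the p changed. At P28, lists called came to 3 and calls lost were microglia (-0.11) and glucocorticoid (0.15). In adults, lists called came to 0, so every call was lost. In the interaction, lists called came to 0 and calls lost were dentate granule (0.21), precursors (0.15), microglia (0.14), endothelial (0.077), choroid plexus (-0.83), immediate early (-0.18), glucocorticoid (-0.20), perineuronal net (0.10), immature neurons (0.23) and interferon (0.27). Averaged, lists called came to 0 and calls lost were interneuron (-0.11), choroid plexus (0.34), immediate early (0.089), glucocorticoid (0.049), neuropeptides (-0.059) and interferon (-0.098). With age in vehicle mice, lists called came to 0 and calls lost were oligodendrocyte (-0.90), precursors (-0.37), endothelial (-0.10), blood (-0.78), immediate early (0.15), potassium channels (0.11), immature neurons (-0.37), interferon (-0.26), chaperones (0.25) and cholesterol (-0.25). From P28 to adult with cannabis, lists called came to 0 and calls lost were dentate granule (0.31), oligodendrocyte (-0.71), precursors (-0.23), microglia (0.098), choroid plexus (-0.99), blood (-0.64), glucocorticoid (-0.22), chaperones (0.15), cholesterol (-0.18) and circadian clock (0.18). By fry the means are likewise as reported. In adults, in the interaction and averaged, 0 lists were called and the same calls were lost. At P28, lists called came to 1 and calls lost were microglia (-0.11), choroid plexus (0.76), immediate early (0.18) and glucocorticoid (0.15). For age in vehicle mice, calls lost were endothelial (-0.10), immediate early (0.15) and chaperones (0.25). For age in cannabis mice, calls lost were precursors (-0.23), microglia (0.098) and chaperones (0.15).

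Within replicates 1 to 3 there are 12 arrays, so fewer samples. At P28, lists called came to 10 and the sign turned for Mgll (-0.010) and Daglb (-0.032). In adults, lists called came to 0, calls lost were interneuron (-0.041), dentate granule (0.090), oligodendrocyte (0.18), precursors (0.063), endothelial (0.023), perineuronal net (0.028), proliferation (0.041) and immature neurons (0.11) and the sign turned for Faah (-0.041). Between ages, calls lost were endothelial (0.043) and perineuronal net (0.087). Averaged, calls lost were neuropeptides (-0.050) and the sign turned for Faah (-0.021). For age in vehicle mice, probes called came to 4 and calls lost were endothelial (-0.071) and immediate early (0.13). In cannabis mice across ages, probes called came to 0. Within replicates 4 and 5 there are 6 arrays, with 1 of each treatment at P28, whose spread is assumed to be that of the other groups. At P28, probes called came to 16 and lists called came to 9, calls lost were glucocorticoid (0.13) and the sign turned for Fkbp5 (-0.026) and interferon (0.006). The correlation of the cannabis effects came to 0.010. In adults, probes called came to 1 and, of the calls, only interneuron, dentate granule and endothelial were kept. For the difference between ages, probes called came to 10 and calls lost were precursors (0.077), endothelial (0.13), immediate early (-0.094), glucocorticoid (-0.22), perineuronal net (0.10) and interferon (0.018). Averaged, probes called came to 7, calls lost were glucocorticoid (0.022) and neuropeptides (-0.069) and the sign turned for Napepld (-0.012) and interferon (0.015). Between the ages of vehicle mice, probes called came to 0 and calls lost were potassium channels (0.11) and cholesterol (-0.11). Across ages in cannabis mice, probes called came to 32 and calls lost were microglia (0.096), blood (-0.47) and glucocorticoid (-0.083).

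Within the first set of 6 in the order of deposit each treatment has 1 adult array, and within the second 1 P28 array, assumed to vary like the other groups. Within the first set the changes were these. At P28, lists called came to 9 and the sign turned for Faah (0.12), Mgll (-0.040) and Daglb (-0.10). The correlation of the cannabis effects came to 0.26. In adults, lists called came to 3, calls lost were interneuron (-0.16) and the sign turned for Slc32a1 (0.034), Cort (0.17), Rfx3 (-0.089), Prox1 (-0.17), Pdgfra (-0.050), Sox18 (-0.12), Slco1a4 (-0.035), Eng (-0.096), Ncan (-0.14), Hapln4 (0.21), Nusap1 (-0.004), Marcksl1 (-0.22), Dpysl5 (-0.20), Napepld (0.081), dentate granule (-0.056), precursors (-0.087), endothelial (-0.11), perineuronal net (-0.022), proliferation (-0.011) and immature neurons (-0.13). In the interaction, lists called came to 6, calls lost were dentate granule (0.010), precursors (0.035), choroid plexus (-0.40), perineuronal net (0.053) and immature neurons (0.026) and the sign turned for microglia (-0.021) and endothelial (-0.062). Averaged, lists called came to 12, calls lost were immediate early (0.018) and glucocorticoid (0.022) and the sign turned for Cort (0.011). In vehicle mice across ages, probes called came to 0, calls lost were endothelial (-0.011) and potassium channels (0.094) and the sign turned for Kcnq5 (-0.052) and Cnr1 (-0.023). With age in cannabis mice, probes called came to 0 and calls lost were dentate granule (0.16) and microglia (0.033). Within the second set they were as follows. At P28, calls lost were microglia (-0.083) and choroid plexus (0.060) and the sign turned for Ttr (-0.15). The correlation of the cannabis effects came to 0.012. In adults, calls lost were precursors (0.14), perineuronal net (0.053) and proliferation (0.067) and the sign turned for Mobp (-0.027), Faah (-0.17), Daglb (-0.032), interneuron (0.019) and oligodendrocyte (-0.045). Between ages, lists called came to 5 and calls lost were dentate granule (0.22), precursors (0.19), microglia (0.12), endothelial (0.048), glucocorticoid (-0.19), perineuronal net (0.080) and immature neurons (0.28). Averaged, calls lost were interneuron (-0.033) and neuropeptides (-0.010) and the sign turned for Cldn2 (-0.007), Ddit4 (0.30), Faah (-0.21) and choroid plexus (-0.042). Across ages in vehicle mice, probes called came to 0, calls lost were endothelial (-0.094), immediate early (0.10) and chaperones (0.10) and the sign turned for Daglb (0.12). For age in cannabis mice, probes called came to 0 and calls lost were precursors (-0.13), microglia (0.093), chaperones (0.022) and cholesterol (-0.11).

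The choroid plexus level as a covariate sets that list itself to 0 by construction, so its lost calls and its sign at 0 are no finding. At P28, calls lost were choroid plexus (0) and the sign turned for Faah (0.067) and Mgll (-0.12). For the difference between ages, calls lost were endothelial (0.060), choroid plexus (0) and immature neurons (0.16). Averaged, calls lost were neuropeptides (-0.050) and the sign turned for choroid plexus (0). With age in vehicle mice, probes called came to 129. From P28 to adult with cannabis, probes called came to 0 and calls lost were oligodendrocyte (-0.21), precursors (-0.16), choroid plexus (0), cholesterol (-0.079) and circadian clock (0.15). Newly called with it were at P28 oligodendrocyte (-0.43, main -0.046), mural cell and meningeal fibroblast (-0.12, main -0.11) and cholesterol (-0.097, main -0.018); in the interaction oligodendrocyte (0.61, main 0.19) and cholesterol (0.15, main 0.062); averaged oligodendrocyte (-0.12, main 0.050) and mural cell and meningeal fibroblast (-0.082, main -0.076); for age in cannabis mice immature neurons (-0.22, main -0.14) and interferon (0.14, main 0.006).

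Lists newly called, summed over the 6 comparisons, numbered 5 with no filter, 2 with the level in all arrays, 3 with own groups, 3 with the replicate block, 6 with averaged probes, 1 with fry, 2 with the block of 4 and 5, 17 with replicates 1 to 3, 30 with replicates 4 and 5, 1 with the block of sets, 21 with the first set, 19 with the second set, 2 with normexp and 9 with the choroid covariate. Most often these were chaperones at P28 (main 0.079, newly called in 7 alternatives), oligodendrocyte in the interaction (main 0.19, newly called in 7 alternatives) and mural at P28 (main -0.11, newly called in 6 alternatives), 1 of them of the other sign, replicates 4 and 5 (0.17).

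Leaving out 1 array at a time gave the following lowest and highest values for results whose call, sign or count changed in at least 1 fit. At P28 the ranges were -0.19 to 0.043 for the correlation of the cannabis effects, 5 to 8 for lists called and 0 to 11 for probes called. At P28 gene values ran from -0.020 to 0.076 for Daglb, -0.11 to 0.070 for Faah and -0.051 to 0.11 for Mgll, signs turning in some. In adults the ranges were 0 to 8 for lists called, 0.035 to 0.086 for proliferation, 0.090 to 0.19 for dentate granule, 0.021 to 0.081 for endothelial, 0.029 to 0.074 for perineuronal net, 0.064 to 0.17 for immature neurons, -0.18 to -0.097 for interneuron, 0.035 to 0.13 for precursors and 0.042 to 0.24 for oligodendrocyte. In adults gene values ran from -0.13 to 0.008 for Napepld, signs turning in some. Between ages the ranges were 6 to 13 for lists called, 0.17 to 0.26 for dentate granule, 0.045 to 0.10 for endothelial, 0.067 to 0.12 for perineuronal net and 0.097 to 0.20 for precursors. Averaged the ranges were 0.019 to 0.072 for glucocorticoid, -0.067 to -0.046 for neuropeptides and 0 to 1 for probes called. Averaged gene values ran from -0.021 to 0.067 for Napepld, signs turning in some. For age in vehicle mice the ranges were -0.13 to -0.071 for endothelial and 28 to 317 for probes called. For age in cannabis mice the ranges were 0.090 to 0.22 for chaperones, -0.28 to -0.18 for precursors and 0 to 102 for probes called.

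Of the values of called lists under alternatives other than left-out arrays, 513 kept direction and side of the threshold, 190 lost the call and 14 turned, and with left-out arrays 773 kept both and 109 lost the call. For named genes the numbers were 1861 kept, 136 lost, 38 gained and 42 turned, and 2402, 128, 13 and 13 with left-out arrays. A fold change of 1.2 as well gave 191 and 5 probes for age in vehicle and cannabis mice.

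Alternatives planned and not run are quantile normalization without background correction, median centring (which moves nothing on values with 1 distribution per array), the second normalized table for probes, lists and the correlation, the slide as a block, detection p in all arrays, and Xist as a covariate, since its level differed too little between arrays. The value table that was planned as an alternative became the main source.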

Other observations

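The fits of lists without 1 array are tests chosen only after the result was seen. Immature neuron genes fell into separate levels among adult cannabis arrays: replicates 2 and 4 were at 9.04 each (log2 intensity), and replicates 1, 3 and 5 at 8.67, 8.66 and 8.61. Adult vehicle arrays lay between 8.61 and 8.79, and the P28 arrays of both treatments between 8.89 and 9.14. Oligodendrocyte precursor markers parted the same arrays, with replicates 2 and 4 at 8.06 and 8.01 and the others at 7.67 to 7.80, and these 2 were also the highest in oligodendrocyte markers, at 10.36 and 10.37 (others 9.72 to 10.09). Without adult cannabis replicate 4 no adult list passed by camera, and without replicate 2, 1 did.

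Ttr ranged from 8.39 to 14.47 (log2 intensity) across the 18 arrays, a 67.5-fold range. The sex-linked list had 3 members above background, and none passed in limma in any contrast (adjusted p of at least 0.404). Kdm5d differed by -0.065 ± 0.10 (SE) with cannabis at P28, by 0.106 ± 0.090 in adults and by -0.107 ± 0.095 with age in vehicle mice. Eif2s3y differed by -0.098 ± 0.187, 0.075 ± 0.168 and -0.263 ± 0.178, and Uty by 0.105 ± 0.066, -0.011 ± 0.059 and 0.124 ± 0.062.

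Of the 35 lists tested, 19 passed by camera in at least 1 contrast and 16 in none. Among neurons and glia, pyramidal neurons of CA1 to CA3 had mean log2 changes with cannabis of 0.028 at P28 and 0.089 in adults (lowest adjusted p over the contrasts 0.189), and astrocytes -0.068 and 0.005 (0.331). Mural cells and meningeal fibroblasts came nearest, with -0.107 and -0.044 (0.0608, at P28). Markers of thalamus were at -0.019 and -0.041 (0.16), of neocortex at -0.032 and -0.031 (0.475) and of striatum at 0.012 and -0.045 (0.2).

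Among functional lists, the endocannabinoid system, with 11 members, was at 0.021 at P28 and 0.051 in adults (lowest adjusted p 0.189). Glutamate receptors were at -0.034 and 0.004 (0.269), GABA-A subunits at -0.036 and -0.042 (0.282) and monoamine receptors and enzymes at 0.027 and 0.014 (0.476). Presynaptic release genes were at -0.017 and -0.051 (0.249), the postsynaptic density at -0.002 and 0.016 (0.239) and neurotrophic signalling at 0.005 and 0.040 (0.349). Oxidative phosphorylation, with 38 members, was at -0.019 and 0.006 (0.0906, for age in cannabis mice), ribosomal proteins, with 31, at -0.015 and -0.009 (0.498) and the oxidative stress list at -0.010 and 0.038 (0.354).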
